A study of Homo sapiens with 9 samples.

How the data were processed

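DNA from U251 cells, an established human glioma line, was measured in 9 libraries of a pooled sgRNA screen. Per the labels' protocols, cells that stably expressed sgRNAs were grown in DMEM with serum and exposed to temozolomide, a DNA-alkylating chemotherapy drug, for 72 hours, and DNA was then isolated for sequencing. The sample titles give 3 doses, 0, 200 and 1500 µM, with 3 libraries each, numbered 1 to 3. The treatment protocol gives the same figures in nM, so the unit of the doses is not settled here, and the titles' unit is printed throughout as a name of the groups. The labels do not state the nuclease, the vector, the time since infection or whether replicate numbers mark separate cultures. P-values that compare libraries therefore measure only the spread between these libraries, which may be technical. No library from before the treatment and no plasmid pool was analysed here.

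The authors deposited 1 table of raw counts per sgRNA for the whole series, with the guide and its target gene in its first columns. Per the submitters' processing notes, cutadapt 1.18, which trims adapters, and MAGeCK 0.5.8, which counts guides and scores screens, were used, and hg19 was named as the genome build. The aligner settings, the allowed mismatches and any filter on guides are not given in the sources used here. The values were whole numbers with different totals in each library, and they were used as counts without change. Guides were named as in the table. Of its 1117 target genes, 1076 had a current symbol in a RefSeq gene table of assembly GRCh38.p14, 40 were matched through a single older symbol, and 1 kept the table's name. No coordinate was used, since the builds differ. No guide was named as non-targeting.

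The table held 11170 guides, 10 per gene, of which 148 were at 0 in all 9 libraries. Total counts per library lay between 1852340 and 2790563, or 166 to 250 counts per guide on average. A count of 0 in a library allows up to 3 counts, which is 1.08 to 1.62 CPM (counts scaled to a common library total) depending on the library. Shares of a single library carry exact Clopper-Pearson 95% binomial intervals. The labels name a PCR-free library kit, and whether the guide region was amplified is not given in the sources used here. No molecular identifiers were stated, so intervals and floors cover counting error only.

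The 10337 guides with at least 10 counts in at least 3 of the 9 libraries were tested. Each pair of doses was compared with edgeR 4.0.16's quasi-likelihood test (TMM factors, robust fit) on the 6 libraries of the pair, without a block, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. A further fit used the dose step, coded 0, 1 and 2, over all 9 libraries. The SE printed for an edgeR log2 fold change was derived from its test. It is the absolute log2 fold change over the square root of the quasi-likelihood F statistic, and is only approximate for guides near 0 counts. Guides were then ranked by their one-sided edgeR p, and a robust rank aggregation gave an exact p per gene and direction under uniform ranks. It used ranks up to 0.25 and the 1116 genes with at least 2 tested guides, and the adjustment was made within each direction. A gene called enriched has guides among the most increased ranks, and a gene called depleted among the most decreased. Of 39 gene lists, 18 had at least 5 measured genes and were tested by the mean over genes of the gene's median guide log2 fold change, against 100000 random gene sets of the same size, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison. The 13 lists with 1 to 4 measured genes were given as values, and 8 lists had no measured gene. The p of the rank aggregation and that of the list test compare guides or genes with each other. They do not measure the spread between libraries. Library measures were compared with exact two-sided permutation tests, which cannot go below 0.1 with 3 against 3 libraries. R 4.3.3, limma 3.58.1, DESeq2 1.42.0, Python with numpy, pandas and scipy were used.

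The groups, tests, lists and the following rule for named genes were fixed before the data were examined. In each comparison and the dose-step fit, up to 10 genes per direction past the gene test were named. Where fewer than 5 passed, the 5 of lowest p were named as not passing, for 1500 against 0 µM and 200 against 0 µM. FBXO5, DOK6, MGMT and the mismatch repair genes were to be given in those comparisons, and so were up to 4 members of each list past its test and up to 5 guides per direction. Genes named outside this rule were chosen after their values were seen.

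Replicate numbers were checked for pairing before the fits were compared. Over 9 pairs of libraries with the same number at different doses, deviations from the dose means correlated at 0.66 to 0.78 across guides. Correlations above 0.1 in all such pairs were the rule for pairing, so the numbers were taken to pair the samples. The pairing comes from the data and the titles' numbers, and guides are not independent replicates. The main design stayed without the block as fixed beforehand, and values with the replicate number as a block are printed beside the calls of the gene and list tests that it changed.

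The functions were tested on simulated data. Counts were simulated for 1500 against 0 µM from the real guide means per replicate number and the dispersion of the blocked fit, with 200 genes changed, and the gene test ran on 1116 genes. Every guide of a changed gene was given the same fold, so recovery of genes whose guides disagree was not measured. Without the block it recovered 60% of 50 genes changed 2-fold upwards, 96% of those changed 4-fold upwards, 46% of those at 0.5-fold and 94% of those at 0.25-fold. With the block the values were 70%, 96%, 62% and 86%. Of 916 unchanged genes, 1 was called in either design. Single guides of the same genes were recovered in 0% of cases without the block at every fold size. With the block 8.84% of guides were recovered at 2-fold, 62.6% at 4-fold, 4.28% at 0.5-fold and 28.7% at 0.25-fold. With 200 genes changed the Benjamini-Hochberg adjustment is laxer than with few, so these rates of genes and guides need not hold for the real screen. There the lowest adjusted guide p at 1500 against 0 µM with the block was 0.999 in edgeR. Of 5000 genes with random ranks, 5.22% had a p under 0.05.

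Alternatives were other scaling factors, other count filters, DESeq2, all 9 libraries in a shared fit, the replicate block, other rank limits, summed counts and fry per gene, camera for the lists, thinned libraries, and leaving out each library. Added after the data were seen were the block together with DESeq2, summed counts or fry, fits without 3 dominant guides, 2 further library measures, library measures without UBE2A.7 or compared within replicate numbers by exact sign flips, and 11 further gene lists, some of genes that share a symbol prefix and some grouped by function.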

Results

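The screen measured which sgRNAs remained in U251 glioma cells after 72 hours of temozolomide, from 3 libraries each at 0, 200 and 1500 µM. The library targeted 1117 genes, most of them of the ubiquitin system, with 10 guides per gene. The series title names FBXO5, an F-box protein that inhibits the anaphase-promoting complex, and DOK6, a docking adaptor, in relation to temozolomide sensitivity. Total counts were 1852954, 2309361 and 1852340 at 0 µM, 2068712, 1979391 and 2462866 at 200 µM, and 2790563, 2544275 and 2111335 at 1500 µM, for replicates 1, 2 and 3.

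Libraries with the same replicate number were alike at every dose. Their levels correlated at 0.79 to 0.89 across tested guides as log2(CPM + 1), whereas libraries of the same dose and other numbers correlated at 0.39 to 0.49. Guides are not independent replicates, so these values describe the libraries and carry no p.

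**Figure D1:**
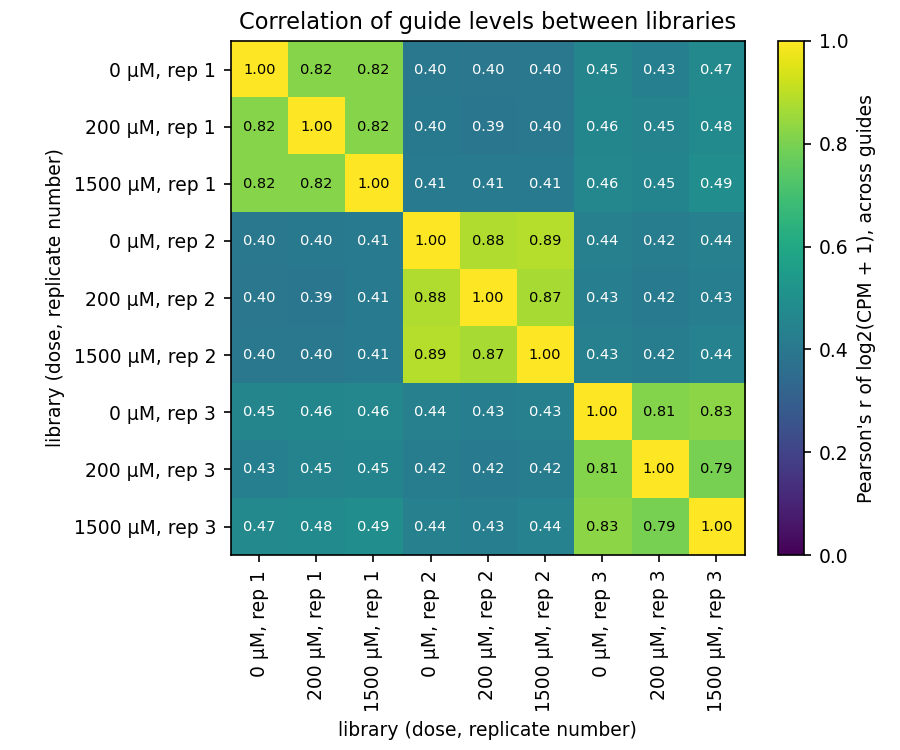
Pearson's correlation of log2(CPM + 1) across the tested guides for each pair of the 9 libraries, ordered by replicate number and then dose. Same-number pairs lie between 0.79 and 0.89, and pairs of other numbers at the same dose between 0.39 and 0.49.

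The comparison of 1500 with 0 µM asked which target genes changed the share of cells that remained at the highest dose. Guides against HUWE1, a HECT-type ubiquitin ligase, passed the gene test as enriched. Their median log2 fold change was 1.33 over 10 guides (SD 2.20 over guides), 8 of 10 guides were higher, and the adjusted p of the rank aggregation on edgeR p-values was 0.0302 with 3 libraries per group. This p was adjusted over the enriched direction alone. A joint adjustment over both directions, which would be stricter, was not run for the rank aggregation. HUWE1 guides were scarce. The 4 with the highest fold changes, HUWE1.1, HUWE1.3, HUWE1.6 and HUWE1.8, had at most 6 counts in any library at 0 µM and reached the minimum of 10 counts only in treated libraries, so the call rests on guides near 0 counts without drug. The summed HUWE1 level was 123 ± 55.1 CPM at 0 µM and 132 ± 65.8 CPM at 1500 µM (SD, n = 3), and the log2 fold change of the summed counts was 0.21 ± 0.61 (SE). HUWE1 was the only gene past the threshold among 1116, and no gene passed as depleted. The call ended with the replicate number as a block (adjusted p = 0.760), with no count filter (0.161), at least 50 counts, the DESeq2 Wald test (0.0864), all 9 libraries in the fit (0.0879), summed counts (0.854) or fry (0.915), and when any of the 3 libraries at 0 µM (0.855, 0.853 and 0.771 without replicates 1, 2 and 3) or replicates 2 or 3 at 1500 µM (0.546 and 0.529) was left out. Without replicate 1 at 1500 µM HUWE1 passed (0.0459), and so did HSPA8.

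The next enriched genes did not pass the gene test. UBA3, a subunit of the NEDD8-activating enzyme, had a median log2 fold change of 0.53. The value was 0.47 for FBXO43, an inhibitor of the anaphase-promoting complex, and 0.39 for CBLB, a RING-type ubiquitin ligase, and these 3 genes had an adjusted p of 0.259 in the rank aggregation on edgeR p-values. DR1, a repressor of RNA polymerase II transcription, had 0.57 and an adjusted p of 0.434. Among depleted genes that did not pass, TRAF3, an adaptor that restrains non-canonical NF-κB signalling, had a median log2 fold change of -1.002 with 9 of 10 guides lower, and FOXL2, a forkhead transcription factor, had -0.61 with all 9 tested guides lower. These and KCTD14, whose median was -0.05 and whose lowest guide, KCTD14.5, had -7.61 ± 2.54 (SE), had an adjusted p of 0.184. BIRC2, a ubiquitin ligase of the NF-κB and apoptosis pathways, had -0.60 with an adjusted p of 0.248, and EGR2, a zinc-finger transcription factor, had -0.65 with 0.255. The summed TRAF3 level was 2156 ± 1246 CPM at 0 µM, 1424 ± 845 CPM at 200 µM and 983 ± 434 CPM at 1500 µM (SD, n = 3).

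**Figure D2:**
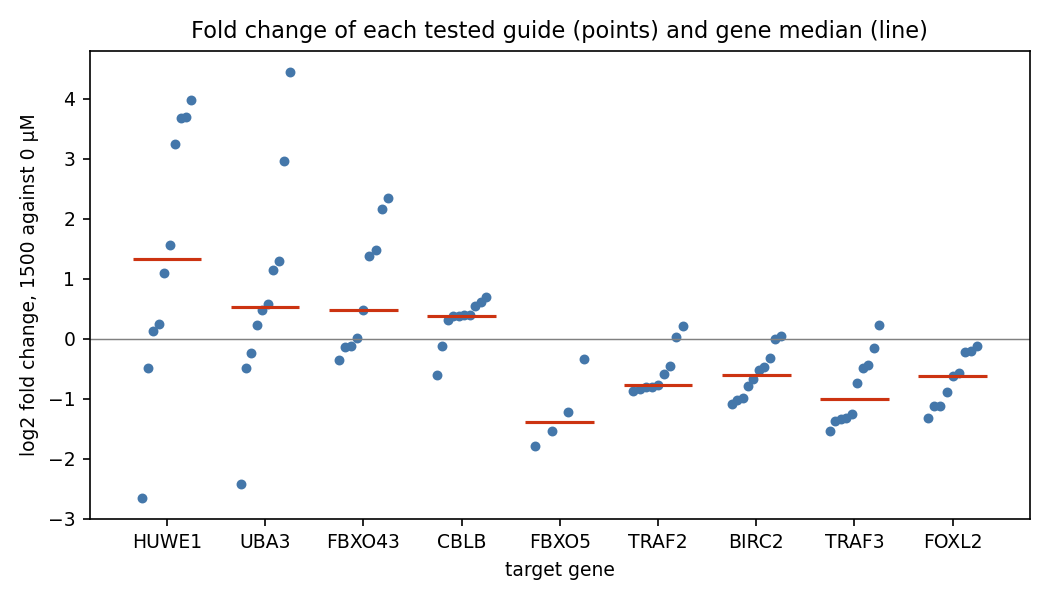
The log2 fold change of each tested guide (points, sorted within a gene) at 1500 against 0 µM for 9 target genes, with the gene median as a line. HUWE1 has a median of 1.33 with 8 of 10 guides above 0, and TRAF3 a median of -1.002 with 9 of 10 guides below 0; FBXO5 has 4 tested guides.

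Among the gene lists, proteasome guides rose at 1500 against 0 µM. The mean over 29 proteasome genes was 0.17 on the log2 scale against -0.07 for all genes, 23 of the 29 lay above that mean, and the adjusted p against random gene sets was 0.00468 by permutation. The call was lost in camera, with an adjusted p of 0.506 with an estimated correlation and 0.151 with a preset correlation. No proteasome gene passed the gene test, over all genes or adjusted over the list alone. PSMC6 had a median log2 fold change of 0.86, PSMA6 of 0.56 and PSMD13 of 0.65, whereas PSMA4 had -0.86. With the replicate block the list missed the threshold (mean 0.16, adjusted p = 0.0888). The direction turned without replicate 3 at 1500 µM (mean -0.10), and the list did not pass without replicate 1 or 2 at 1500 µM (means 0.14 and 0.10). Without replicate 1, 2 or 3 at 0 µM its mean was 0.33, 0.39 and 0.43. The permutation p was 0.0981 against random sets matched on mean count, which could hold proteasome genes themselves.

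The other 17 tested lists did not pass. The 11 NF-κB genes had a mean of -0.30 (adjusted p = 0.0841 by permutation), with BIRC2, TRAF2 and TRAF3 past the gene test as depleted adjusted over the list alone. With the block only TRAF3 held (adjusted p = 0.00907, against 0.177 for BIRC2 and 0.537 for TRAF2). Without replicate 3 at 0 µM the NF-κB list passed (mean -0.43, adjusted permutation p = 0.0154). It did not pass without replicate 1 or 2 at 0 µM (means -0.26 and -0.20). Nor did it pass without replicate 1, 2 or 3 at 1500 µM (means -0.32, -0.45 and -0.18) or with the block (mean -0.18, adjusted permutation p = 0.301). The cullin-RING and neddylation list had 0.10 (adjusted p = 0.0644), and it passed without replicate 2 or 3 at 0 µM (means 0.31 and 0.28). It did not pass without replicate 1 at 0 µM (mean 0.14) or without replicate 1, 2 or 3 at 1500 µM (means 0.14, 0.06 and 0.11). With the block its mean was 0.19 (adjusted permutation p = 0.0877). UBA3 passed the gene test adjusted over this list alone. Adjusted in this way, HUWE1 also passed in the HECT ligase list, FBXO43 in the anaphase-promoting complex, DDB1 in nucleotide excision repair and BIRC2 in intrinsic apoptosis. The block ended these calls, with adjusted p-values of 0.441 for HUWE1, 0.951 for FBXO43, 0.433 for DDB1 and 0.226 for BIRC2, and that of UBA3 (0.225). With the block AXIN1 passed instead as enriched over the Wnt list alone (0.0485) and EED as depleted over the SWI/SNF and Polycomb list (0.00228). UBE2A passed over the translesion synthesis list (0.0391) through UBE2A.7, and without UBE2A.7, DCUN1D1.3 and EP300.4 its adjusted p was 0.441. Values adjusted over a list alone are not adjusted over the lists. No gene passed over all genes with the block in the rank aggregation (lowest adjusted p 0.555 enriched and 0.102 depleted). Of 11 lists added after the data were seen none passed in any pair of doses, with or without the block, and the lowest adjusted permutation p was 0.103, for the SUMO and UFM1 pathway at 1500 against 0 µM (mean 0.11 over 22 genes, 0.540 with the block). Of DNA damage lists, translesion synthesis had a mean of 0.05 over 8 genes (adjusted p = 0.550) and nucleotide excision repair 0.09 over 6 genes (adjusted p = 0.479) by permutation. Too small to test, the 4 measured genes of the Fanconi anaemia pathway had 0.20, the 4 of homologous recombination -0.01 and the 4 of the replication checkpoint -0.08.

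**Figure D3:**
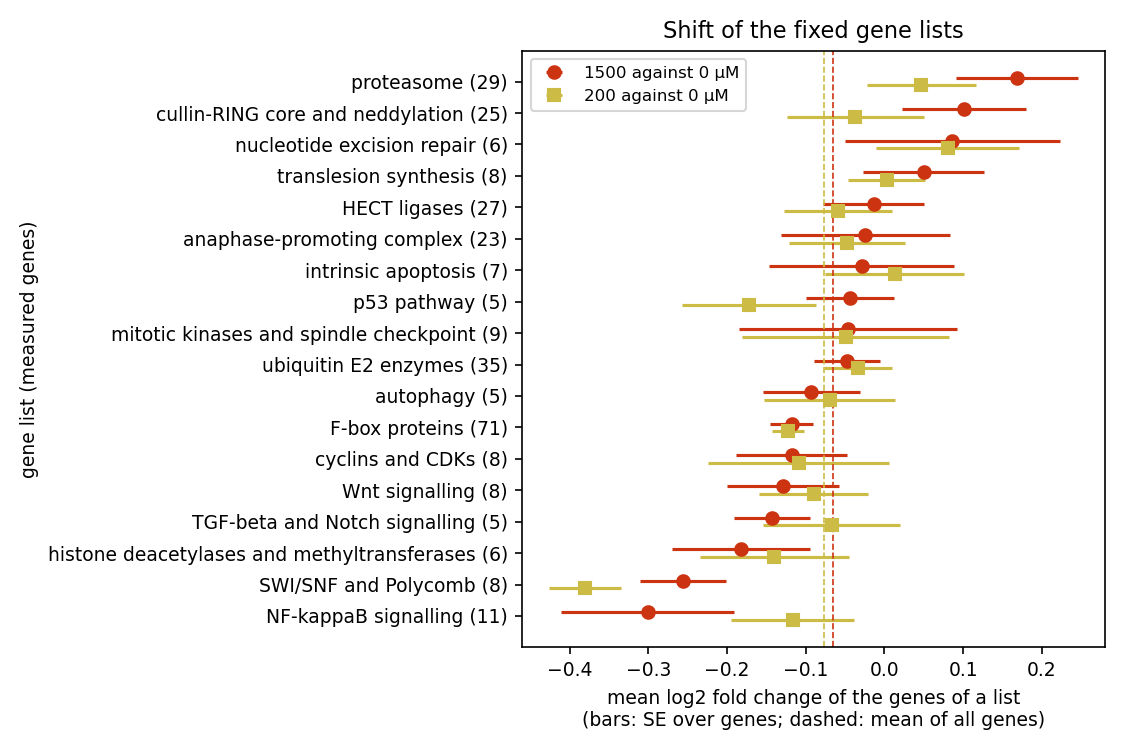
Mean over genes of the median guide log2 fold change for the 18 tested lists, at 1500 against 0 µM (circles) and 200 against 0 µM (squares), with the SE over genes as bars and the mean of all genes as dashed lines. The proteasome list lies highest at 1500 µM (0.17) and the NF-κB list lowest (-0.30).

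No single guide passed at 1500 against 0 µM in edgeR's quasi-likelihood test. Of 10337 guides, 21 had an unadjusted p under 0.05, against 61 with DESeq2, which also called none. In the simulation edgeR without the block recovered 0% of changed guides at every fold size. The lack of calls therefore does not speak against changed guides. The lowest p-values among higher guides belonged to TRIM69.10, SENP1.1, HSPA8.2, CDK2.3 and ASB16.7, and among lower guides to TNIP2.10, CUL2.4, MVB12A.8, RNF138.10 and KCTD14.5, each with an adjusted p that rounded to 1.00. With the replicate block in edgeR 270 guides had an unadjusted p under 0.05 and none passed. Uniform p-values would put a share of 0.05 of the tested guides there. The edgeR counts of every comparison and of the dose step, with and without the block, lay below that share. The larger count with the block is therefore no excess. With the replicate block and DESeq2, 6 guides passed. UBE2A.7, DCUN1D1.3 and EP300.4 were higher, and PELI3.10, TRIM45.10 and TRIB2.6 were lower.

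UBE2A.7, a guide against a RAD6-type ubiquitin-conjugating enzyme, was the most abundant guide in every library at 1500 µM. It was also the most abundant in replicates 2 and 3 at 0 and at 200 µM. In replicate 2 its share fell from 1.13% of the counts at 0 µM to 0.768% at 200 µM (exact Clopper-Pearson intervals of 1.12 to 1.15% and 0.756 to 0.780%). Its level was 5900 ± 5849 CPM at 0 µM, 11030 ± 10327 CPM at 200 µM and 110240 ± 100380 CPM at 1500 µM (SD, n = 3). It held 6.07%, 18.6% and 4.97% of the counts of replicates 1, 2 and 3 at 1500 µM, with exact Clopper-Pearson intervals of 6.05 to 6.10%, 18.5 to 18.6% and 4.94 to 4.997%. In the fit without the block its log2 fold change at 1500 against 0 µM was 4.20 ± 1.86 (SE), and with the block it was 4.31 ± 0.67. DCUN1D1.3, against a neddylation co-factor, and EP300.4, against a histone acetyltransferase, had blocked log2 fold changes of 2.90 ± 0.76 and 1.62 ± 0.43 (SE). Summed over its guides, UBE2A passed as enriched with the block (log2 fold change 4.05 ± 0.56, edgeR adjusted p = 0.00481), a sum set by UBE2A.7.

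**Figure D4:**
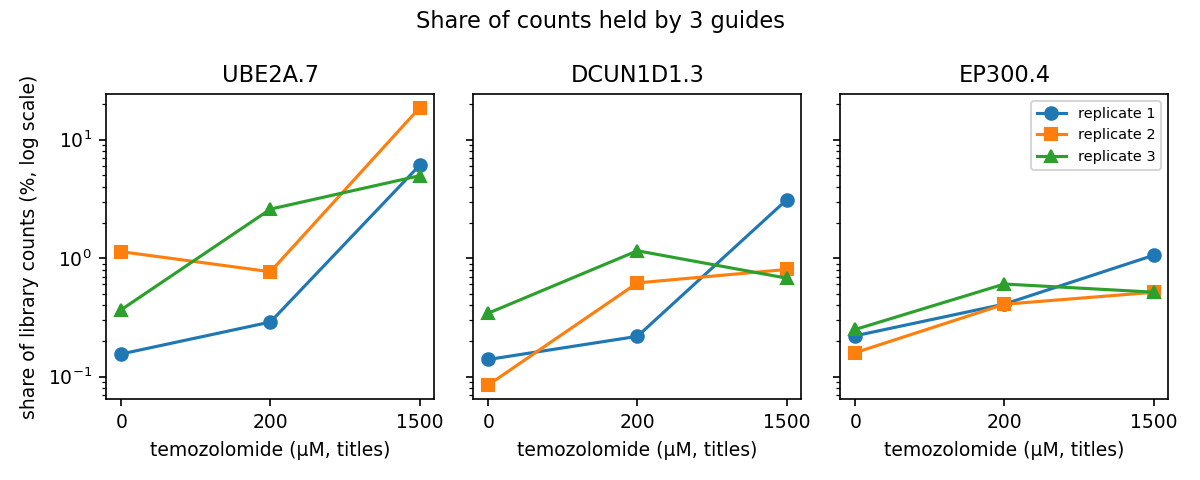
Share of each library's counts (log scale) held by UBE2A.7, DCUN1D1.3 and EP300.4 at the 3 doses, which are spaced evenly and not to scale, with lines joining libraries of the same replicate number. UBE2A.7 reaches 6.07%, 18.6% and 4.97% at 1500 µM.

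At 200 against 0 µM, no gene passed the gene test in either direction among 1116. The 5 enriched genes of lowest p were HUWE1, MAEA, a subunit of the CTLH ubiquitin ligase, POLE3, a DNA polymerase epsilon subunit, SMU1, a splicing factor, and RNF40, a histone H2B ubiquitin ligase. Their median log2 fold changes were 1.31, 0.68, 0.65, 2.10 and 0.89, each with an adjusted p of 0.656, and SMU1 rested on 2 guides of which 1 was higher. The 5 depleted genes of lowest p were RNF126, FOXL2, TMBIM6, RNF114 and TRIM64B, with medians of -0.55, -0.23, -0.29, -0.33 and -0.25 and adjusted p-values of 0.876 to 0.898. Without replicate 3 at 200 µM, UBE2W passed as enriched. No guide passed in edgeR, with 14 guides at an unadjusted p under 0.05, or in DESeq2, with 40. With the block and DESeq2, 6 guides passed. The lowest guide p-values belonged to PSMC3.8, TCP1.4, CDCA3.5, MED11.3 and RNF4.4 among higher guides and to TRIM64B.3, B2M.1, TMBIM6.9, RNF149.10 and BTBD1.3 among lower guides.

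No gene list passed at 200 against 0 µM. The 8 Polycomb genes of the SWI/SNF and Polycomb list, which act in gene silencing, all lay below the mean of all genes. Their mean was -0.38 against -0.08, with an adjusted p of 0.0707 by permutation, 0.00825 in camera with a preset correlation and 0.180 with an estimated correlation. CBX8 had a median log2 fold change of -0.53 and SUZ12 of -0.41. The list passed with no count filter (mean -0.40) and by the mean of the guides. It did not pass with the replicate block (mean -0.39, adjusted permutation p = 0.211). The proteasome list had a mean of 0.05 (adjusted p = 0.104), and it passed without replicate 2 or 3 at 0 µM (means 0.29 and 0.33) and with no count filter (mean 0.14). Without replicate 1, 2 or 3 at 200 µM its mean was -0.27, -0.20 and -0.03, and with the block it was -0.09 (adjusted p = 0.958). The mean was -0.12 for the NF-κB list (adjusted p = 0.869). HUWE1 passed the gene test adjusted over the HECT ligase list alone, but not with the block (adjusted p = 1.00). With the block BIRC3 and XIAP, UBE2H (0.0354), TNKS and TNKS2 (both 0.0220) passed as enriched over their lists alone, and CBX8 and RING1 (both 0.0328) as depleted. These values are not adjusted over the lists. Over all genes none passed with the block in the rank aggregation (lowest adjusted p 0.512 enriched and 0.793 depleted). Summed XIAP counts went from 47043 to 1589, from 1761 to 1589 and from 1029 to 3738 in replicates 1, 2 and 3. The guide XIAP.8 alone went from 46599 to 503, from 718 to 604 and from 466 to 3096. It held most of the change of the sums in replicates 1 and 3. The 4 Fanconi anaemia genes had 0.20 and the 4 homologous recombination genes -0.16.

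Between the doses, at 1500 against 200 µM, proteasome guides rose and NF-κB guides fell in the test against random gene sets. Neither list passed in camera with an estimated correlation (adjusted p = 0.702 for both), with the block (0.585 and 0.536) or with no count filter (0.989 and 0.320). The proteasome mean was 0.15 with the block and 0.01 with no count filter. The NF-κB mean was -0.12 with the block and -0.18 with no count filter. The proteasome list had a mean of 0.16 against 0.01 for all genes, with 21 of 29 genes above and an adjusted p of 0.0115 by permutation, and PSMC2, PSMD12, PSMD13 and PSMA4 had medians of 0.07, 0.38, 1.03 and -0.39. The 11 NF-κB genes had a mean of -0.19, with 10 below the mean of all genes and an adjusted p of 0.0424. Among them BIRC2 had a median of -0.37 with 10 of 10 guides lower, TRAF3 of -0.52, TAB2 of -0.36 and RIPK1 of -0.06. BIRC2 passed the gene test as depleted adjusted over the list alone and over the intrinsic apoptosis list alone. SIRT2 passed as enriched adjusted over the histone deacetylase and methyltransferase list alone, and MAD1L1 over the mitotic kinase and spindle checkpoint list alone. The block ended these calls (adjusted p = 0.0824 and 0.105 for BIRC2, 0.101 for SIRT2 and 0.0635 for MAD1L1), and TRAF3 passed with it as depleted over the NF-κB list alone (0.00907). Over all genes none passed with the block in the rank aggregation (lowest adjusted p 0.871 enriched and 0.376 depleted). The NF-κB list also missed the threshold by the mean of the guides (adjusted p = 0.262). Without replicate 3 at 1500 µM the proteasome mean was -0.10, and without replicate 1 or 2 at 1500 µM or replicate 2 at 200 µM the list did not pass (means 0.13, 0.06 and 0.44); without replicate 1 at 200 µM the mean was 0.52. Left out in turn, replicate 1, 2 or 3 at 1500 µM and replicate 1 or 2 at 200 µM ended the NF-κB call, with means of -0.27, -0.29, -0.07, -0.13 and -0.08, and without replicate 3 at 200 µM the mean was -0.31. Without that library the cullin-RING and neddylation list passed (mean 0.21, adjusted permutation p = 0.0371). No gene and no guide passed at 1500 against 200 µM in the main tests, though MBIP passed as enriched without replicate 1 and BIRC2 as depleted without replicate 3 at 200 µM. In edgeR 21 guides had an unadjusted p under 0.05, and 33 in DESeq2; with the block and DESeq2, 43 guides passed. Among higher guides the lowest p-values belonged to MOCS3.2, PSMC2.9, RNF141.7, NLK.2 and CUL9.1, and among lower guides to MVB12A.8, SIAH1.10, KCTD14.5, ANAPC5.5 and FZD4.7.

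The dose-step fit over 9 libraries asked for guides whose share moved in 1 direction over the doses. HUWE1 was enriched, with a median log2 fold change of 0.67 per step, 8 of 10 guides higher and an adjusted p of 0.0400 in the rank aggregation on edgeR p-values. That p, too, was adjusted over the enriched direction alone. No other gene passed. With the block HUWE1 had an adjusted p of 0.749, and the call ended without any of the libraries at 0 µM (0.526, 0.568 and 0.722), without replicate 3 at 200 µM (0.0992) or without any at 1500 µM (0.101, 0.455 and 0.683). It also ended with no count filter (0.163), at least 50 counts, the DESeq2 Wald test (0.439), summed counts (0.880) or fry (0.910). TRAF3 had a median of -0.49 per step and an adjusted p of 0.301, and it and CCDC50 passed as depleted without replicate 2 at 1500 µM. With the block, on counts summed per gene, TRAF3 fell by 0.46 ± 0.07 (SE) per step on the log2 scale (edgeR adjusted p = 0.00572). In fry with the block TRAF3 was the only gene depleted, with an adjusted p of 0.0243. EED, a Polycomb subunit, had -0.28 ± 0.06 per step in the blocked sums, with a two-sided adjusted p of 0.0894, and passed when each direction was adjusted apart. In edgeR 35 guides had an unadjusted p under 0.05 and none passed, and in DESeq2 100 guides had one and none passed.

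FBXO5 was among the scarcest targets. Of its 10 guides 4 were tested, and FBXO5.1 was at 0 in all 9 libraries. Its summed level was 53.2 ± 55.8 CPM at 0 µM, 36.7 ± 43.7 CPM at 200 µM and 46.6 ± 21.1 CPM at 1500 µM (SD, n = 3). The median log2 fold change of its tested guides was -1.38 at 1500 against 0 µM (adjusted p for depletion 0.878 in the rank aggregation on edgeR p-values), -0.62 at 200 against 0 µM (0.984) and -0.21 at 1500 against 200 µM (0.990). These medians cover the 4 tested guides only. Counts summed over all 10 guides rose from 20 to 63 in replicate 1 and from 62 to 131 in replicate 3 at 1500 against 0 µM. They fell from 243 to 130 in replicate 2, so the direction is not settled. FBXO5 did not pass the gene test in these comparisons, and the SE of its guides' log2 fold changes at 1500 against 0 µM was 1.87 for FBXO5.9 to 2.92 for FBXO5.2. DOK6, MGMT and the mismatch repair genes were not analysed here.

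Library evenness was compared between doses with exact permutation tests, whose smallest two-sided p is 0.1. Guides at 0 counts made up 11.2 ± 1.27% of the guides at 0 µM, 13.9 ± 1.26% at 200 µM and 11.97 ± 1.63% at 1500 µM (SD, n = 3). The exact p was 0.1 for 200 against 0 µM and 0.6 for 1500 against 0 µM. Within replicate numbers the share at 0 was higher in 3 of 3 pairs at 200 and at 1500 than at 0 µM, with an exact sign-flip permutation p of 0.25, the smallest that 3 pairs allow. The top 1% of guides held 13.6 ± 3.23% of the counts at 0 µM, 11.97 ± 0.712% at 200 µM and 20.3 ± 6.78% at 1500 µM. The exact p was 0.1 for 1500 against 200 µM and 0.2 for 1500 against 0 µM, and the share was higher in 3 of 3 pairs at 1500 than at 0 µM. Without UBE2A.7 it was 13.2 ± 3.44% at 0 µM, 10.9 ± 0.398% at 200 µM and 11.7 ± 1.97% at 1500 µM, lower in 3 of 3 pairs at 1500 than at 0 µM. The Gini index was 0.657 ± 0.0364, 0.629 ± 0.0128 and 0.651 ± 0.0449, with exact p-values of 0.3 to 0.8. It was lower than at 0 µM in 3 of 3 pairs at 200 µM, and higher in 1 of 3 at 1500 µM. Without UBE2A.7 the index was 0.656 ± 0.0366, 0.624 ± 0.0175 and 0.613 ± 0.0251, lower in 3 of 3 pairs at 1500 than at 0 µM. After Benjamini-Hochberg adjustment over 15 tests no value was below 0.25.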

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

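The fits that join the replicate block with DESeq2, summed counts or fry, and those without 3 dominant guides or UBE2A.7, were chosen after the data were seen. The HUWE1 call at 1500 against 0 µM held with DESeq2 size factors, with total counts and with other rank limits. It gave 0 genes with no count filter, at least 50 counts, the DESeq2 Wald test, all 9 libraries in the fit, the replicate block, the block with DESeq2 or fry, the block without the dominant guides, summed counts and fry. Summed counts with the block gave 1 gene, UBE2A in place of HUWE1. A threshold of 0.25 gave 5 genes, and leaving out a library gave 0 to 2. In the dose step no count filter, at least 50 counts, DESeq2, the block alone, with DESeq2 or without the dominant guides, summed counts and fry gave 0 genes, the block with fry gave 1 (TRAF3), the block with summed counts 2, and leaving out a library 0 to 2. At 200 against 0 µM leaving out a library gave 0 to 1 genes, and at 1500 against 200 µM 0 to 1, with 1 at a threshold of 0.25. Guide calls rose from 0 to 6, 6, 43 and 6 with the block and DESeq2 (1500 against 0, 200 against 0, 1500 against 200 µM and the dose step). Gene lists past the test at 1500 against 0 µM numbered 1, with 0 under the block and under camera with either correlation and 0 to 3 without a library. At 200 against 0 µM the count was 0, with 2 without a count filter, 1 by the mean of the guides, 1 in camera with a preset correlation and 0 to 1 without a library. At 1500 against 200 µM it was 2, with 0 without a count filter, under the block and under camera with either correlation, 1 by the mean of the guides and 0 to 3 without a library. For gene list proteasome the mean turned to -0.10 without replicate 3 at 1500 µM, against 0 µM and against 200 µM, and without the other libraries it reached 0.43 and 0.52. The cause was not tested for these changes. Without UBE2A.7 the difference in the share of the top 1% of guides was -1.52 percentage points for 1500 against 0 µM and 0.715 for 1500 against 200 µM, and that of the most abundant guide 0.624 and 0.928, since UBE2A.7 held most of that rise. Of gene calls adjusted over a list alone, TRAF3 at 1500 against 0 µM held with the block and the other 12 did not, while 11 passed only with it. These calls were not adjusted over the lists, directions and comparisons, so some may arise by chance. Of the remaining values, 131 library measures, 69 values of FBXO5 and 614 list values stayed on their side of the threshold or within their spread, though 105 of all 648 list values, past the threshold in neither setting, lay on the other side of the mean of all genes. Total counts moved the median guide log2 fold change from -0.09 to 0.09 at 200 against 0 µM and from 0.01 to -0.13 at 1500 against 200 µM. Factors from non-targeting guides were not run, since the table names none. A count of 0 allows up to 1.62 CPM, against a median guide level at 0 µM of 2.71 CPM for HUWE1 and 2.33 CPM for FBXO5.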

Other observations

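The tests on UBE2A.7, DCUN1D1.3 and EP300.4, on scarce guides, on levels without drug and on the blocked sums with both directions adjusted together were chosen only after the result was seen. Guide levels without drug set target groups apart. At 0 µM the median guide level of a gene had a median of 64.4 CPM over genes. It was 5.56 CPM for the proteasome list, 11.9 CPM for mitotic kinases and the spindle checkpoint, 17.1 CPM for the anaphase-promoting complex and 19.9 CPM for the cullin-RING core and neddylation, with adjusted permutation p-values of 9e-05 to 0.00018. F-box proteins, with 77.2 CPM, lay above the other genes (adjusted permutation p = 0.00745). FBXO5 ranked 18 from the lowest of 1117 genes at 2.33 CPM and HUWE1 ranked 22 at 2.71 CPM. No earlier library was analysed here, so these levels do not separate loss during growth from a low share in the pool. XIAP.8 had 46599 counts in replicate 1 at 0 µM and 466 to 3641 in the other 8 libraries.

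The guides UBE2A.7, DCUN1D1.3 and EP300.4, which passed only with the block and DESeq2, were higher at 1500 than at 0 µM, UBE2A.7 by 34.7-fold, 17.9-fold and 13.1-fold in replicates 1, 2 and 3. An effect of that size shared by all guides of a target is argued against. The other 23 tested guides of these genes had a median blocked log2 fold change of -0.0454 (SD 0.80), below the smallest rise of 1.62. By gene the median of the other guides was 0.09 for UBE2A, -0.28 for DCUN1D1 and -0.16 for EP300. Since the 3 guides were picked for their rise, a weaker shared effect, or one of only some guides, is not excluded. A clone grown up in a single culture would raise a guide in 1 replicate number. Together 8 of 9 pairs of guide and number rose over 2-fold, short of the 9 set as the bound, so the guides were then taken singly, though the block that picked them favours rises in every number: UBE2A.7 rose in 3 of 3, its lowest log2 fold of 3.72 beyond 1 by more than its SD of 0.72, which argues against it for this guide, while EP300.4 (3 of 3, lowest 2.01-fold and within its spread of the bound) and DCUN1D1.3 (2 of 3) leave it open. One added template would keep a fixed ratio, but UBE2A.7 over DCUN1D1.3 differed by 11.8-fold between the libraries at 1500 µM; a resistant clone present before the cultures were parted, or an off-target effect of a guide, may still account for the rise and was not tested.

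The rise of the proteasome list at 1500 against 0 µM may come from its low counts. Random gene sets matched on mean count had a mean of 0.03 against 0.17 for the list, with a permutation p of 0.0981, which does not separate the list from scarce genes. The sets could hold proteasome genes themselves, which were 9 of the 56 genes in the lowest bin of mean count. This can draw the mean of the sets toward that of the list. The mean count also covered all 9 libraries, those at 1500 µM included. Fewer cell divisions under the drug, a biological candidate, would spare all groups scarce without drug. The 53 genes of the anaphase-promoting complex, cullin-RING and mitotic lists lay 0.0879 above all genes (95% bootstrap interval -0.04 to 0.21), below the 0.23 of the proteasome. The bound set beforehand left out the proteasome list's own spread, and with it the difference of 0.15 had an interval of -0.05 to 0.34, so the explanations cannot be told apart here.

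Treated libraries held fewer guides with 1 to 9 counts, by 4.4 percentage points of detected guides. Greater depth is argued against, since libraries thinned to the same total differed by -3.61 points (5.07 ± 1.86% in 6 treated and 8.68 ± 1.60% in 3 untreated libraries, exact permutation p = 0.0357). This p ignores the replicate numbers, and none was computed within them. At 0, 200 and 1500 µM the thinned share was 9.06, 4.18 and 4.21% in replicate 1. It was 10.05, 6.43 and 8.12% in replicate 2 and 6.92, 3.01 and 4.46% in replicate 3. All 6 treated libraries had more guides at 0 than the untreated library of their number, as fewer template molecules would need, but the two-sided permutation p within numbers was 0.0741 for this count, the smallest it can reach, and 0.111 for the mean difference of 1.73 percentage points. Fewer template molecules therefore stay open, as does whether fewer cells survived or less DNA was used, which was not tested.

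Other splits of the libraries bear on the counts of calls. For 1500 against 0 µM the gene test gave 1 gene and 0 as the highest of the other splits, for 200 against 0 µM 0 and 2, and for 1500 against 200 µM 0 and 1, and single guides gave 0 in every split of the 3 pairs. With 10 splits of 6 libraries, of which 1, 10 and 10 gave as many genes and 10 as many guides, no share under 0.05 can be reached. Among the 4 splits that part every same-numbered pair, the highest other count was 0. In those 4 splits the block with DESeq2 gave 6 guides against 2 at most elsewhere for 1500 against 0 µM, 6 against 4 for 200 against 0 µM and 43 against 14 for 1500 against 200 µM, with 1 split as large in each, too few splits for a share under 0.05. In the dose step chance was not excluded for HUWE1: 11 of 100 regroupings gave as many genes, at most 2, and so did 8 of 100 within replicate numbers, at most 1. For single guides 100 of 100 gave at least the 0 calls, and the highest, 1216, came from the regrouping that put each replicate number on its own step, which points to the structure by replicate number. For the blocked sums 2 of 100 regroupings within numbers, the real one among them, gave as many genes as the 2 called with each direction adjusted apart (TRAF3 and EED), and the highest other was 3. With both directions adjusted together only TRAF3 was called, and 2 of 100 gave as many, the highest other 1. Chance was excluded at a share of 0.05 for these 2 counts taken alone, but the fit was added after the data were seen, is 1 of several that were run, and the same block gave 0 genes in the rank aggregation.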
